A study of Mus musculus with 12 samples.

How the data were processed

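Gene expression was measured in liver RNA from 12 adult male mice, 3 in each of 4 groups. The groups combined 2 genotypes, wild-type and liver-null for Txnrd1, with 2 injections, saline or acetaminophen (APAP, 100 mg/kg, given into the peritoneum). Livers were taken 8 hours after injection, per the labels' protocols. RNA was amplified in a single labelling cycle to biotin-labelled cRNA, per the labels' protocols, and each liver was read on its own Affymetrix array. The replicate number of a mouse came from the end of its title, and no number is shared between groups, so no mice were paired.

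The deposited values are log2 expression values per probe set, made by the authors with RMA, a method that corrects background, normalizes and summarises the probes of an Affymetrix array, per the submitters' processing notes. The version of RMA, its background model and whether all arrays were normalized together are not given in the sources used here. The table holds 22690 probe sets with no detection calls. The median log2 value of an array lay between 2.91 and 2.99. Probe sets near these values probably have little signal over background, so fold changes that start there may be understated. For arrays, depth has no count, and the number of arrays limits the precision.

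The arrays fell into 2 sets that the labels do not name. The upper quartile of the values was 5.49 to 5.58 on 4 arrays (wild-type saline 10, wild-type APAP 14, liver-null saline 16 and liver-null APAP 17) and 5.73 to 5.85 on the other 8. Each group has 1 array in the smaller set. The cut was put at the largest gap between arrays in this upper quartile. The smaller set is called the second batch and the other the first batch. Results are given without batch in the model, as fixed beforehand, with counts from a fit with batch as a covariate, or values within each batch, beside the counts of genes and lists and beside some of the single results. No pair of arrays held the same values: at most 0.0088% of probe sets were equal in any pair, and pairwise correlations across probe sets were 0.986 to 0.998.

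Probe sets were named from the platform annotation supplied with the table, which may be old. Of the 22690 probe sets, 64 are Affymetrix controls, 20380 have 1 gene symbol, 691 have several and 1555 others have none listed. Entrez identifiers of 20351 probe sets matched the RefSeq table of assembly GRCm38.p6, and 0 symbols were updated through it. No genome coordinates are printed, because the build behind the array annotation is not named. A gene was represented by its probe set with the highest mean, among probe sets with 1 symbol. This gave 12393 genes, of which 4956 have 2 or more probe sets. A gene was tested where its value exceeded the 40th percentile of the array on at least 3 of the 12 arrays, which left 8469 genes and removed 3924. No further normalization was applied. Probe sets of closely related genes, such as the glutathione S-transferases Gstm3 and Gstm4, can bind each other's transcripts.

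Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit, contrasts, eBayes with default settings). The model had a mean for each of the 4 groups over all 12 arrays, with 8 residual degrees of freedom and 3.43 prior degrees of freedom. A gene was called changed at a Benjamini-Hochberg adjusted p under 0.05 over the 8469 genes, two-sided, with no fold limit. Unless another test is named, every adjusted p of a gene comes from this fit. SE is the standard error of a fitted log2 difference, and ± after a group mean is the SD of 3 arrays. The 5 comparisons, the alternatives, the gene lists and the rule for naming genes were chosen before the data were examined. A further comparison, genotype averaged over the 2 treatments, was added after seeing the data.

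The rule for named genes took Txnrd1 always. Per comparison it took the 10 largest rises and the 10 largest falls among changed genes for which every array of 1 group lay beyond every array of the other. Per list and comparison it took up to 4 changed members in each direction, or, where none passed, the 2 members with the largest difference, as values. A gene named in 1 comparison could be given in the others.

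Of 39 gene lists, 38 had at least 5 tested members; the list of erythroid markers did not and was left out. Lists were tested with camera, which asks whether a list moves relative to all other genes, with a preset correlation of 0.01 between genes and Benjamini-Hochberg adjustment over the lists. Beside it stand camera with an estimated correlation, which allows for genes of a list varying together from liver to liver, and fry, which asks whether the genes of a list move on balance 1 way and compares them with no other gene. For each list, the members past the threshold over all genes and adjusted over the list alone were counted. List means per array are the mean over members of the log2 value minus the gene's mean over the 12 arrays. For the comparison over both treatments, these means were tested with an exact permutation test, two-sided, over all 200 splits of the arrays by genotype within each treatment.

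The fit was tested on simulated data with 8469 genes, the spread of the real arrays and 200 changed genes, in 20 simulations. For the genotype comparison in saline, 23.7% of genes changed by 0.5 log2 were recovered, 73.2% of those changed by 1 and 97.4% of those changed by 2, and 5.08% of calls were false. For the interaction, recovery was 6.3%, 47.8% and 87.8%, and 5.2% of calls were false. The simulated genes varied independently of each other, unlike those of real lists.

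Alternatives covered the filter, quantile normalization, median centring, the choice of probe set, the arrays in the fit, the variance model, array weights, a fold limit of 1.5 and leaving out each array in turn. Added after seeing the data were batch as a covariate, only the 8 arrays of the first batch, batch with an estimated correlation, and leaving out 2 arrays with a high acute phase list (wild-type APAP 12 and liver-null saline 4).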

Results

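Liver RNA was profiled on Affymetrix arrays from 12 male C57BL6/J mice, 8 weeks old, in 4 groups of 3. Mice received saline or 100 mg/kg acetaminophen (APAP), a painkiller whose oxidised metabolite is captured in the liver by glutathione. Wild-type mice were compared with mice labelled liver-null for Txnrd1, in which albCre, a Cre recombinase made in hepatocytes, disrupts a conditional allele. Txnrd1 encodes the cytosolic thioredoxin reductase, an enzyme that uses NADPH to reduce thioredoxin. The series title names a shifted metabolic bias and protection against APAP toxicity, and the comparisons below ask which liver transcripts differed between the genotypes, and which differed 8 hours after APAP. The 12 livers came from separate mice, and pairwise correlations between arrays were 0.986 to 0.998.

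Txnrd1 was higher, not lower, in the arrays labelled liver-null. Its expressed probe set read 9.61 ± 0.19 on the log2 scale in wild-type saline livers and 10.35 ± 0.10 in liver-null saline livers, a 1.67-fold difference (log2 0.74, SE 0.12, adjusted p = 0.0206, n = 3 per group, limma). After APAP it read 9.68 ± 0.08 and 10.44 ± 0.12, a 1.70-fold difference (log2 0.76, SE 0.12, adjusted p = 0.0146, limma). All 6 arrays labelled liver-null lay between 10.26 and 10.58, above the 6 wild-type arrays at 9.43 to 9.81. The other 2 probe sets of Txnrd1 had group means of 1.40 to 2.00 and did not differ between the genotypes, with log2 differences of -0.03 and -0.11 in saline. Where these probe sets lie relative to the deleted part of the gene was not analysed here, so Txnrd1 does not check the genotype labels, and the groups are named as labelled throughout. In the fit with batch Txnrd1 passed in both treatments (adjusted p = 0.00945 and 0.00752, limma). It missed the threshold in fits to the 6 arrays of each comparison, where the differences stayed at 0.74 and 0.76 with adjusted p = 0.128 and 0.0598 (limma). Leaving out wild-type saline 8 or 9 or liver-null saline 4 or 5 also ended the call in saline, with Txnrd1 differences of 0.66 to 0.79, and leaving out wild-type APAP 13 or any of the 3 liver-null APAP arrays ended it after APAP, with 0.69 to 0.80. Averaged over both treatments the difference was 0.75 (adjusted p = 0.000858, limma).

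**Figure D1:**
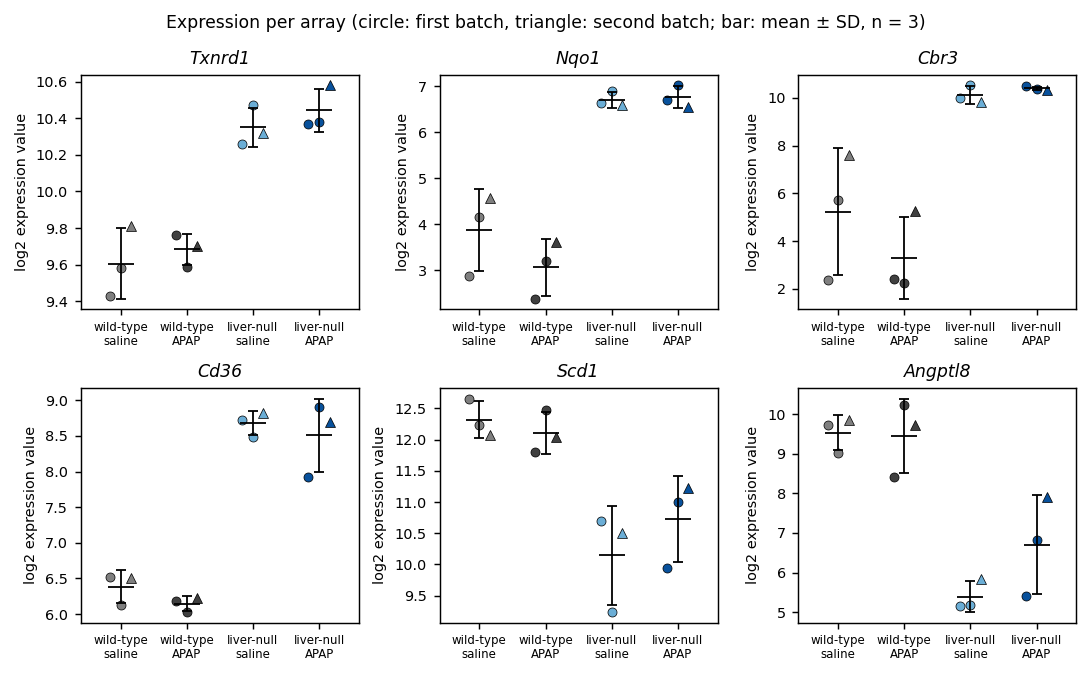
Log2 expression values of 6 genes on each of the 12 arrays, by group; points are single livers (circles first batch, triangles second batch) and bars are the mean ± SD of 3 livers. Txnrd1, Nqo1, Cbr3 and Cd36 lie higher on all 6 arrays labelled liver-null than on all 6 wild-type arrays, and Scd1 and Angptl8 lie lower.

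In saline, many detoxification transcripts and a few genes tied to lipid storage were higher in the livers labelled liver-null, and the desaturases Scd1, Fads1 and Fads2 were lower. The lipid droplet genes Fitm1 and Cidec rose 9.29-fold (log2 3.22, SE 0.60) and 8.36-fold (log2 3.06, SE 0.49). Fitm1 had a log2 difference of 2.27 without wild-type saline 8 and lost its call without any 1 of the 3 liver-null saline arrays, and Cidec ranged from 2.47 without liver-null saline 4 to 3.69 without liver-null saline 16 and lost its call without wild-type saline 8 or 9 or liver-null saline 5. Ctse, the gene of the protease cathepsin E, was called higher from 1 probe set (14.9-fold; log2 3.89, SE 0.40), but its other probe set read lower in the livers labelled liver-null (2.22 ± 0.03 against 4.06 ± 0.76), so no direction is read for Ctse. Nqo1, a quinone reductase and standard NRF2 target, rose 7.09-fold, and Cd36, a fatty acid transporter, rose 4.91-fold from 6.38 ± 0.23 to 8.68 ± 0.17. Pparg, a nuclear receptor that drives lipid storage, rose 3.61-fold. Of 11 other tested genes of lipid droplets and PPAR-gamma 0 passed (median log2 difference -0.091). That set leaves out the genes already seen to rise, which leans it towards no difference. Cbr3 and Plin4 had larger differences than Fitm1 (log2 4.89 and 3.36) but did not pass (adjusted p = 0.0674 and 0.0654, limma), and passed with batch as a covariate (adjusted p = 0.0272 and 0.0293, limma). Angptl8, a secreted regulator of lipoprotein lipase, fell 17.6-fold, from 9.53 ± 0.44 to 5.39 ± 0.39. Scd1, the main stearoyl-CoA desaturase of liver, fell 4.53-fold from a level of 12.32 ± 0.30.

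Altogether 54 of 8469 genes differed between the genotypes in saline, 31 higher and 23 lower (limma, adjusted p under 0.05). For all 54 the 3 arrays of 1 group lay beyond the 3 of the other, as they did for 15.2% of all genes. Chance gives 10% for arrays without a batch, but each group here mixes the batches. After APAP, 5.02% of genes separated the arrays in wild-type livers and 4.89% in livers labelled liver-null. Beyond the genes above, the 10 largest rises held the long noncoding transcript Snhg11, the glutathione transferases Gsta2 (4.15-fold) and Mgst3 (3.97-fold), and Tceal8. The 10 largest falls held Cela1, Ank3, Susd4, the ketone-body enzyme Aacs, Pla1a, the desaturase Fads2 (2.61-fold), the sterol carrier Stard4 (2.39-fold) and Abcb10, with log2 differences from -1.93 to -1.25. Cela1 is a digestive elastase that stood on a list of pancreas, fat and muscle carry-over, of whose 5 tested genes it alone passed in saline.

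Of 24 tested NRF2 targets, 10 rose in saline and 0 fell (20 rose when adjusted over the list alone), with a mean log2 difference of 1.22. NRF2 is the transcription factor that switches on antioxidant and detoxification genes. Besides Nqo1 and Gsta2, the risen members included Gstm3 and Gstm4 (2.97-fold and 2.96-fold). The list passed camera (adjusted p = 2.61e-29) and fry (adjusted p = 0.00547), but not camera with an estimated correlation (adjusted p = 0.109). Of 20 glutathione S-transferases, which couple glutathione to reactive compounds, 5 rose and 0 fell (10 rose and 1 fell when adjusted over the list alone; camera adjusted p = 8.52e-09, adjusted p = 0.197 with an estimated correlation, fry adjusted p = 0.0263). The 2 lists share 6 tested genes. The risen NRF2 targets also held Srxn1, which repairs oxidised peroxiredoxins (2.43-fold), glutathione reductase Gsr (1.69-fold) and Ugdh, which makes UDP-glucuronate (2.07-fold). Outside the NRF2 list, transketolase Tkt of the pentose phosphate pathway rose 1.63-fold. Of the 18 genes of glutathione and cysteine synthesis, 1 rose (Gsr) and 1 fell, the transsulfuration enzyme Cbs (log2 difference -0.94).

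Of 20 tested genes of fatty acid and triglyceride synthesis, 4 fell in saline and 0 rose (11 fell and 1 rose when adjusted over the list alone): Scd1, Fads2, Fads1 (log2 -1.01) and Elovl5 (-0.91). The list passed camera (adjusted p = 1.24e-07) and fry (adjusted p = 0.0288), but not with an estimated correlation (adjusted p = 0.246). Of 17 genes of cholesterol synthesis and uptake, 2 fell, Stard4 and Sc5d (8 when adjusted over the list alone; camera adjusted p = 1.01e-09, adjusted p = 0.324 with an estimated correlation, fry adjusted p = 0.0742). Of 19 hepatocyte secretory and male-biased genes, 2 fell, the complement gene C6 (-1.19) and the organic anion transporter Slco1a1 (-0.93), and 6 when adjusted over the list alone (camera adjusted p = 9.19e-07, adjusted p = 0.136 with an estimated correlation, fry adjusted p = 0.00547). Of 16 stellate cell and fibroblast markers 0 passed over all genes and 5 fell when adjusted over the list alone (camera adjusted p = 1.04e-05, adjusted p = 0.295 with an estimated correlation). The acute phase list also passed camera upward with 0 of 25 members past the threshold (adjusted p = 8.96e-05, adjusted p = 0.648 with an estimated correlation). Its mean was higher by 1.09 on liver-null saline 4 than the average over arrays. In all, 12 of 38 lists passed camera in saline, 12 with batch as a covariate, 0 with an estimated correlation and 5 by fry.

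With batch as a covariate, 243 genes differed between the genotypes in saline (104 higher, 139 lower), among them all 54. The mean NRF2 difference was 1.44 in the first batch and 0.77 in the second, and that of fatty acid synthesis -0.93 and -0.58. Single arrays set the count: it was 10 without wild-type saline 8 or without wild-type saline 9, 13 without liver-null saline 4, 11 without liver-null saline 5, and 92 without wild-type saline 10. It was 19 in a fit to the 6 arrays alone and 1323 with array weights, which gave wild-type saline 9 a weight of 4.63 and wild-type saline 10 a weight of 0.363.

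**Figure D2:**
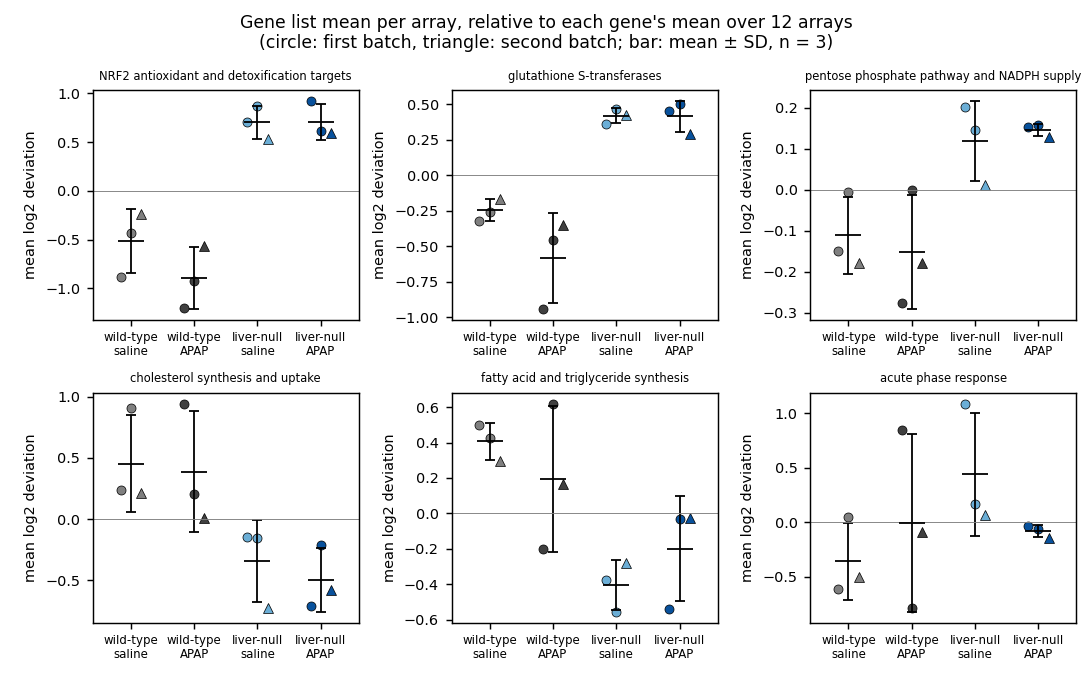
Mean log2 deviation of 6 gene lists on each of the 12 arrays, relative to each gene's mean over the arrays; circles are first-batch and triangles second-batch livers, and bars are the mean ± SD of 3 livers. NRF2 targets lie at 0.53 to 0.92 on the arrays labelled liver-null and at -1.20 to -0.24 on the wild-type arrays, and the acute phase list is highest on liver-null saline 4 (1.09) and wild-type APAP 12 (0.84).

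After APAP the genotypes differed in many of the same detoxification genes. Cbr3, a carbonyl reductase and NRF2 target, was 137-fold higher in the livers labelled liver-null (log2 7.10, SE 1.09), at 10.40 ± 0.07 against 3.30 ± 1.71. Its wild-type APAP arrays read 2.40, 2.23 and 5.27, the first 2 near background. Without wild-type APAP 14 the Cbr3 difference was 8.08, and without wild-type APAP 12 or 13 or liver-null APAP 2 or 3 Cbr3 lost its call, with 6.56 to 7.10. Plin4, a lipid droplet coat protein, was 26.2-fold higher, Fitm1 13.2-fold and Nqo1 12.9-fold. The small heat shock gene Hspb1 was 6.19-fold higher, at 7.60 ± 0.62 against 4.97 ± 0.34. Among the genes that passed, falls were smaller and led by Susd4 (log2 -1.68) and Cela1 (-1.60), while the larger difference of Angptl8 (-2.74) did not pass (adjusted p = 0.0605, and 0.0225 with batch as a covariate, limma). Nfe2l2, the gene of NRF2 itself, was 1.78-fold lower (log2 -0.83, SE 0.16, adjusted p = 0.0429).

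In this comparison 65 genes differed, 49 higher and 16 lower (limma). For all 65 the arrays of the groups did not overlap, as for 13.9% of all genes. The other large rises were in Cidec (9.57-fold), Gsta2 (8.85-fold), the lectin Lgals1 (7.45-fold), Mgst3 (7.38-fold) and the heme transporter Slc48a1 (6.66-fold). The other large falls, with log2 differences from -1.56 to -0.81, were in Tnfaip8l1, the clock-linked repressor Bhlhe40, Cyp4a31, Stard4, Snx6, the fatty acid binding protein Fabp2 and Grb14. Cbr3, Nqo1 and Cidec had wild-type APAP means of 2.36 to 3.30, close to the array medians, so their folds may be understated, which was not tested.

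Of the 24 NRF2 targets 14 were higher after APAP and 0 lower (21 higher when adjusted over the list alone), with a mean log2 difference of 1.61. This list passed every list test: camera (adjusted p = 1.83e-41), camera with an estimated correlation (adjusted p = 0.0377) and fry (adjusted p = 0.000905). No list passed with batch as a covariate and an estimated correlation. Of the 20 glutathione S-transferases 6 were higher (10 when adjusted over the list alone; camera adjusted p = 1.46e-16, adjusted p = 0.0517 with an estimated correlation, fry adjusted p = 0.00204). Of the 13 genes of the pentose phosphate pathway and NADPH supply, 2 were higher, Pgd (2.07-fold) and Tkt (1.80-fold), and 4 when adjusted over the list alone (camera adjusted p = 0.000682, adjusted p = 0.24 with an estimated correlation, fry adjusted p = 0.0369). Of the 17 cholesterol genes 1 was lower, Stard4, and 8 when adjusted over the list alone (camera adjusted p = 3.67e-15, adjusted p = 0.231 with an estimated correlation). Of the 20 fatty acid synthesis genes 0 passed over all genes and 6 fell and 1 rose when adjusted over the list alone (camera adjusted p = 0.00277, adjusted p = 0.488 with an estimated correlation). Of 18 heat shock genes 1 was higher, Hspb1 (camera adjusted p = 0.000633, adjusted p = 0.531 with an estimated correlation). In all, 14 of 38 lists passed camera, 12 with batch as a covariate, 1 with an estimated correlation and 3 by fry.

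With batch as a covariate 185 genes differed after APAP (125 higher, 60 lower), among them all 65. The mean NRF2 difference was 1.83 in the first batch and 1.16 in the second. The count was 35 without wild-type APAP 12, 32 without wild-type APAP 13, 21 without liver-null APAP 2, 29 without liver-null APAP 3, 39 in a fit to the 6 arrays alone and 210 with array weights.

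The genotype differences in the 2 treatments, which share no array, went together. Of the 86 genes changed in either, 33 were changed in both, 27 higher and 6 lower, where independent lists would share 0.179 and 0.0435. All 54 genes of the saline comparison had the same sign after APAP, and all 65 of the APAP comparison the same sign in saline. Across all 8469 genes, which are not independent replicates, the log2 differences correlated with Pearson r = 0.697 and Spearman rho = 0.53. With batch as a covariate 98 genes were shared.

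**Figure D3:**
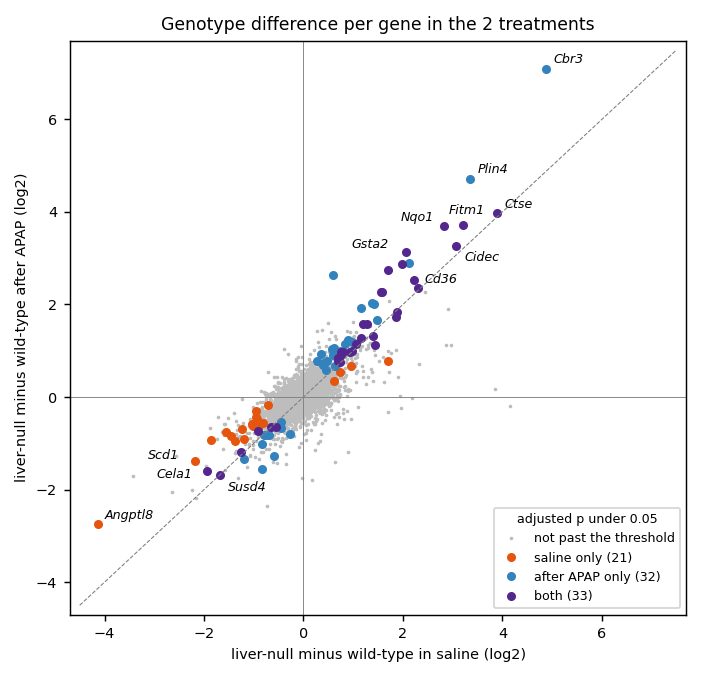
Log2 difference between livers labelled liver-null and wild-type livers in saline (horizontal) and after APAP (vertical) for 8469 genes, with the line of equal differences dashed. Coloured points passed an adjusted p of 0.05 in saline alone (21 genes), after APAP alone (32) or in both (33), and every coloured point has the same sign in both treatments.

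Averaging the genotype difference over the 2 treatments, a comparison added after seeing the data, set 6 livers labelled liver-null against 6 wild-type livers. Several lipogenic genes were lower: Elovl6, a fatty acid elongase, fell 5.09-fold, fatty acid synthase Fasn 4.35-fold and the lipogenic regulator Mid1ip1 3.29-fold, beside Angptl8 (10.8-fold) and Scd1 (3.44-fold). Me1, the cytosolic malic enzyme that yields NADPH and a member of both the lipogenic and the NRF2 lists, rose 2.40-fold instead. Gclc, the rate-limiting enzyme of glutathione synthesis, rose 1.94-fold, and the APAP conjugate exporter Abcc3 rose 2.36-fold. Cyclin D1 (Ccnd1), which drives cell cycle entry, fell 4.51-fold, and Hsd3b5, a male-biased steroid enzyme, fell 5.93-fold (adjusted p = 0.0454, limma). The Hsd3b5 call was lost in 12 of 24 alternatives, and its log2 difference was -1.82 without liver-null saline 4.

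In this comparison 378 genes differed, 193 higher and 185 lower (limma), and 269 of them separated all 6 livers of each genotype. Of the 24 NRF2 targets 20 rose and 0 fell (22 adjusted over the list alone), and of the 20 glutathione S-transferases 9 rose and 0 fell (12 rose and 1 fell adjusted over the list alone). Of the 13 genes of the pentose phosphate pathway and NADPH supply 4 rose, Me1, Pgd (1.76-fold), Tkt (1.71-fold) and Idh2 (1.44-fold), which is 4 adjusted over the list alone too. Of 17 cholesterol genes 6 fell (15 adjusted over the list alone), among them Dhcr7 (2.41-fold), Idi1 (2.25-fold) and Fdft1 (1.94-fold). Of 20 genes of fatty acid and triglyceride synthesis 8 fell and 1 rose, Me1 (9 fell and 1 rose adjusted over the list alone). Of 12 genes of glycogen metabolism 2 rose, the branching enzyme Gbe1 (1.97-fold) and Ppp1r3c (2.07-fold), and 2 adjusted over the list alone. Of 19 hepatocyte secretory and male-biased genes 5 fell (7 adjusted over the list alone), among them Hsd3b5, C6 (2.08-fold) and C8a (1.51-fold).

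The mean of a list per liver was compared between the genotypes by an exact permutation test over 200 splits, whose smallest possible p is 0.005. At that smallest p and an adjusted p of 0.0271 over 38 lists stood 7 lists. The splits were not restricted to keep the batches balanced between the genotypes, so these p-values take no account of batch. NRF2 targets were higher in livers labelled liver-null (0.71 ± 0.16 against -0.71 ± 0.36 on the log2 scale, n = 6 per genotype, exact p = 0.005), as were glutathione S-transferases (0.42 ± 0.08 against -0.42 ± 0.28), pentose phosphate and NADPH genes (0.13 ± 0.06 against -0.13 ± 0.11), glycogen metabolism (0.13 ± 0.14 against -0.13 ± 0.09) and glutathione peroxidases and other peroxide enzymes (0.09 ± 0.10 against -0.09 ± 0.06). Cholesterol genes (-0.42 ± 0.28 against 0.42 ± 0.40) and hepatocyte secretory genes (-0.21 ± 0.16 against 0.21 ± 0.11) were lower. Apart from the peroxide enzymes, each of these lists separated the 6 livers of 1 genotype from the 6 of the other. The margin was narrow for glycogen metabolism, at -0.019 on liver-null saline 16 against -0.029 on wild-type saline 9. It was narrow too for the pentose phosphate list, at 0.011 on liver-null saline 16 against -0.001 on wild-type APAP 13. Fatty acid and triglyceride synthesis, at -0.30 ± 0.24 against 0.30 ± 0.29, gave an exact p of 0.015 and an adjusted p of 0.0633, and did not pass. By camera 12 lists passed, and 12 with batch as a covariate, 0 of them with an estimated correlation (NRF2 targets adjusted p = 0.0631), and 10 passed fry.

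With batch as a covariate 882 genes differed over both treatments (435 higher, 447 lower), among them all 378. The count was 208 without wild-type saline 8, 224 without wild-type saline 9, 250 without wild-type APAP 13, 239 without liver-null saline 5, 215 without liver-null APAP 2, 233 without liver-null APAP 3, 590 after quantile normalization and 1409 with array weights.

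In wild-type livers no gene passed the threshold 8 hours after APAP. Fos and Jun, immediate early transcription factor genes, had log2 differences of 1.10 (SE 0.34) and 1.48 (SE 0.56), and the chaperone gene Dnajb9 0.55 (SE 0.16), none of which passed. Gsta2 (-1.09, SE 0.39) and Mgst3 (-0.94, SE 0.32) leaned lower, and the acute phase genes Lcn2 and Orm2 read 2.00 (SE 1.88) and 1.57 (SE 1.00). The limma fit called 0 genes, with 143 genes at an unadjusted p under 0.05 where chance alone gives 423, and the smallest adjusted p was 1. With batch as a covariate the count was 0 as well, with 434 genes unadjusted and a median SE of 0.126 against 0.17 without batch. The wider spread of the fit without batch enlarges its unadjusted p-values, here and in the liver-null and interaction comparisons below. A count under 423 in that fit is therefore no sign of fewer changes than chance. Every other setting run also called 0 genes.

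The lists moved little after APAP in wild-type livers. Single arrays set the size of these means. NRF2 targets had a mean log2 difference of -0.38 and glutathione S-transferases -0.34, with 0 members past the threshold over all genes and 0 adjusted over the list alone (camera adjusted p = 5.11e-06 and 6.97e-07, adjusted p = 0.887 for both with an estimated correlation). Endoplasmic reticulum chaperones had a mean of 0.17 and immediate early genes 0.23 (camera adjusted p = 4.77e-05 and 0.00122, adjusted p = 0.887 for both with an estimated correlation). The acute phase list had a mean of 0.35 (camera adjusted p = 0.000462, adjusted p = 0.887 with an estimated correlation), which became -0.08 without wild-type APAP 12. Without that array NRF2 targets were at -0.228, glutathione S-transferases at -0.156 and chaperones at 0.048. NRF2 targets were at -0.241 and no longer passed camera without wild-type saline 10, and immediate early genes were at 0.122 without wild-type APAP 13. In all, 9 of 38 lists passed camera, 9 with batch as a covariate, 0 with an estimated correlation and 0 by fry. The log2 differences of all genes correlated between the batches with r = 0.134 across genes.

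In livers labelled liver-null no gene passed after APAP either. Hspb1 had a log2 difference of 1.11 (SE 0.46), Jun 1.19 (SE 0.56) and the phosphatase gene Dusp6 0.95 (SE 0.42), none of which passed. The acute phase genes Orm2 and Saa3 had differences of -2.77 (SE 1.00) and -1.97 (SE 0.92), and the macrophage receptor gene Marco -1.97 (SE 0.99), which did not pass. The limma fit called 0 genes, with 59 at an unadjusted p under 0.05 against 423 by chance, and with batch as a covariate 0 genes and 243 unadjusted. A fit to the 8 arrays of the first batch called 1 gene. The acute phase list had a mean of -0.52 (camera adjusted p = 1.41e-07) and heat shock genes 0.28 (camera adjusted p = 1.93e-06), both with an adjusted p of 0.625 with an estimated correlation and 0 members past the threshold. Neither passed camera without 1 array: the acute phase mean was -0.195 without liver-null saline 4, and the heat shock mean 0.086 without liver-null saline 16. Of 38 lists 13 passed camera, 7 with batch as a covariate, 0 with an estimated correlation and 0 by fry, and 2 passed camera without liver-null saline 4. The log2 differences of all genes correlated between the batches with r = -0.025.

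Whether the response to APAP differed between the genotypes was tested with the interaction term, and no gene passed. Orm2, an acute phase gene, had a log2 value of -4.34 (SE 1.42), the largest among the list members given as values, followed by Lcn2 (-3.69, SE 2.66), and Hspb1 had 2.04 (SE 0.65). Igfbp1, a stress-induced growth factor binding protein, had -2.21 (SE 0.89) and the hormone gene Fgf21 -2.09 (SE 1.34). Among NRF2 targets Cbr3 had 2.21 (SE 1.54) and Gsta2 1.09 (SE 0.56). The limma fit called 0 genes, with 109 at an unadjusted p under 0.05 against 423 by chance, and with batch as a covariate 0 genes and 326 unadjusted. So a gene past the threshold after APAP and not in saline, such as Hspb1, or Cbr3 and Plin4 in the fit without batch, was not shown to differ more between the genotypes after APAP. Of 38 lists 12 passed camera, 13 with batch as a covariate, 0 with an estimated correlation and 0 by fry.

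The APAP responses of the 2 genotypes, which share no array, shared 0 changed genes and had r = -0.121 and rho = -0.042 across genes. The genotype difference in saline and the APAP difference in wild-type livers share the 3 wild-type saline arrays. Their log2 differences correlated with r = 0.264 across genes, and 100 simulations of unchanged groups against shared controls gave 0.499. The covariance was 0.0165 against a simulated 0.0224. The simulated noise took the spread of the fit without batch, with a median SE of 0.17 against 0.126 with batch as a covariate. The second-batch arrays lie evenly over the groups, so their shift widens that spread but cancels from group differences. The simulated covariance may thus be too high, and the simulation does not decide whether the 2 differences are related. The 3 shared arrays are too few to split, and 0 genes were changed in both.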

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

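The interaction was planned, as were the counts over other splits for the 5 comparisons fixed beforehand; the tests on the acute phase list, on probe sets without a single gene symbol, the splits for the comparison over both treatments, and the division of splits by batch, were chosen only after the results were seen.

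Acetaminophen (APAP) shifted 12 lists differently in the 2 genotypes by camera on the interaction, with 0 member genes past the threshold in limma and no list passing with an estimated correlation. The values are the mean log2 response in livers labelled liver-null minus that in wild-type livers. They were -0.867 for the acute phase response, -0.308 for endoplasmic reticulum chaperones, -0.402 for cytokines and chemokines, -0.272 for ATF4 targets of the integrated stress response, -0.912 for infiltrating monocyte and neutrophil markers and -0.146 for fatty acid oxidation. Positive values were 0.387 for NRF2 targets, 0.418 for fatty acid and triglyceride synthesis, 0.362 for heat shock genes, 0.332 for glutathione S-transferases, 0.261 for stellate cell markers and 0.238 for hepatic transporters. Single arrays moved several of these: without liver-null saline 4 the fatty acid oxidation list was 0.025, ATF4 targets -0.044, chaperones -0.125, cytokines -0.246 and monocyte and neutrophil markers -0.493, and ATF4 targets were -0.117 without wild-type APAP 12. Leaving out each array in turn gave 0.235 to 0.569 for NRF2 targets, 0.220 to 0.631 for fatty acid synthesis, 0.172 to 0.533 for heat shock genes and 0.152 to 0.450 for glutathione S-transferases. On liver-null saline 4 and wild-type APAP 12 stood the highest means of monocyte and neutrophil markers (1.24 and 0.83), endoplasmic reticulum chaperones (0.48 and 0.30) and cytokines (0.39 and 0.38). Without these 2 arrays their interactions were -0.108, 0.001 and -0.120, and that of ATF4 targets 0.111, with cytokines alone of these still past camera. Of 100 drawn splits of the arrays by treatment within each genotype, 31 gave 12 or more lists, with a highest other count of 21, so chance is not excluded. For genes the real count was 0, which 100 of 100 splits reach by construction, and the highest other count was 576, which points to a structure of the arrays. Of the other splits, 38 left 1 second-batch array in each group, as the real one does, and all gave 0 genes, and the 576 came from the 61 that spread the second batch unequally. The array batch is therefore a candidate source of that count.

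The acute phase list, with the lowest camera p of these, had a mean of 1.09 on liver-null saline 4 and 0.84 on wild-type APAP 12, and between -0.78 and 0.17 on the other 10 arrays. Without these 2 arrays its interaction was -0.116 (adjusted p = 0.42), but they were picked for their high values, so a smaller interaction follows by construction and whether the responses reflect a state of 2 single livers stays open. The interaction was -0.987 in the first batch and -0.627 in the second, which holds a single array per group and so has no spread between livers, and a part of the array batch stays open. An exchange of the 2 arrays is argued against: the NRF2 mean of liver-null saline 4 exceeded that of wild-type APAP 12 by 1.903, as their labels have it. A treatment response that differs between the genotypes stays open too. The second batch, which holds neither of these 2 livers, also gave a negative value, from a single array per group. The remaining first-batch livers leaned the opposite way. Wild-type APAP 13 read -0.783 against -0.61 and 0.047 on wild-type saline 8 and 9. Liver-null APAP 2 and 3 read -0.035 and -0.057 against 0.166 on liver-null saline 5, a smaller fall.

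Probe sets with no or several gene symbols lie outside the comparisons of genes. Of 1200 such probe sets above the same expression filter, 7 differed between the genotypes in saline, 9 after APAP and 32 over both treatments, with 0 in the APAP comparisons and the interaction (limma). No gene is named from them.

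Other splits of the arrays gave fewer changed genes than the genotypes. In saline the real split gave 54 genes and the highest other split 0, so 1 of 10 splits reached 54, and after APAP the real split gave 65 and the highest other 0, again 1 of 10. With 10 splits a share under 0.05 cannot be reached. Over both treatments the real split gave 378 genes and the highest other 1, so of 100 drawn splits only the real one reached 378. That share is under 0.05, but the comparison was added after seeing the data. Most other splits mix the genotypes within groups, which widens the spread and lowers their counts, so 378 against 1 overstates the contrast. For APAP the real count was 0 in both genotypes, which every one of the 10 splits reaches by construction, so these splits test nothing (highest other 1 in wild-type livers and 2 in livers labelled liver-null). The number of lists passing camera did not stand out in any comparison. In saline 4 of 10 splits gave 12 or more lists (highest other 14), and 3 of 10 after APAP gave 14 or more (highest other 15). For APAP 7 of 10 splits gave 9 or more in wild-type livers (highest other 16) and 2 of 10 gave 13 or more in livers labelled liver-null (highest other 14). Over both treatments 25 of 100 splits gave 12 or more (highest other 18), so chance is not excluded there.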

How the results depend on the processing

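Batch as a covariate, the first batch alone, batch with an estimated correlation and leaving out 2 arrays were chosen only after the results were seen; the other alternatives were planned.

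Ctse, given below, has probe sets that differ in opposite directions. The other probe sets of Txnrd1, also given below, lie near background and did not differ between the genotypes. Among the settings run for the other named genes no genotype difference reversed. Those settings used the probe set with the highest mean or the mean of all probe sets. Another probe set with the opposite direction would therefore not show by itself as a reversal. In saline, 485 of 646 alternative values of 34 named results kept direction and threshold and 161 lost the threshold. After acetaminophen (APAP) these were 454 and 97 of 551, and over both treatments 1463 and 239 of 1702. For the lists of the genotype comparisons, 165 of 192, 176 of 224 and 248 of 264 values kept both, and 0 reversed. For the APAP lists, 97 of 144 kept both in wild-type livers and 117 of 207 in livers labelled liver-null, with 6 and 1 reversed, and 184 of 263 for the interaction with 1 reversed.

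Quantile normalization gave 104 genes in saline and 590 over both treatments. Trend and robust settings gave 121 in saline and 98 after APAP. Array weights gave 1323 in saline, 210 after APAP and 1409 over both treatments. A 1.5-fold limit left 224 over both treatments, by its construction. A fit to the arrays of the comparison alone, with fewer arrays, gave 19 in saline and 39 after APAP. Except for the fold limit and the fewer arrays, the cause was not tested.

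Txnrd1 lost its adjusted p but kept its direction in several settings. Median centring gave 0.78 in saline and 0.74 after APAP, the mean of its 3 probe sets 0.20 and 0.18, and the arrays of the comparison alone 0.74 and 0.76. The other probe sets had the opposite sign, at -0.03 and -0.02 for the first and -0.11 and -0.19 for the second. Both lie near background and did not differ between the genotypes. In the first batch alone Txnrd1 rose 0.70 after APAP, and without the 2 arrays with a high acute phase list 0.79 in saline and 0.80 after APAP. The cause was not tested.

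With an estimated correlation the number of shifted lists was 0 for genotype in saline, 0 for APAP in wild-type livers, 0 for APAP in livers labelled liver-null, 1 for genotype after APAP, 0 for the interaction and 0 for genotype over both treatments. With batch and an estimated correlation it was 0 in all 6. By fry it was 5, 0, 0, 3 and 0 in the first 5 of these. Fry compares a list with no other genes, so its counts answer another question.

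Batch as a covariate gave 243 genes in saline, 185 after APAP and 882 over both treatments, 98 genes shared between the treatments, and 7 lists for APAP in livers labelled liver-null. The first batch alone gave 117 genes in saline and 1 for APAP in livers labelled liver-null. Without the 2 arrays with a high acute phase list there were 26 genes in saline, 36 after APAP and 225 over both treatments. The lists were then 5 for APAP in wild-type livers, 3 in livers labelled liver-null and 6 for the interaction. The direction against other genes reversed for fatty acid synthesis (mean -0.015) and the acute phase response (-0.079) with APAP in wild-type livers, and for transporters in the interaction (0.046). The cause was not tested.

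Leaving out each array in turn gave 10 to 92 genes in saline, 21 to 59 after APAP and 208 to 416 over both treatments. Txnrd1 ranged from 0.66 to 0.84 in saline and 0.69 to 0.80 after APAP. Lists for APAP in livers labelled liver-null ranged from 2 to 12. Among lists that reversed against the other genes, the mean for APAP in wild-type livers ranged from -0.427 to -0.015 for fatty acid and triglyceride synthesis, 0.024 to 0.161 for fatty acid oxidation, -0.079 to 0.734 for the acute phase response and 0.030 to 0.233 for pericentral markers. Interferon-stimulated genes for APAP in livers labelled liver-null ranged from -0.328 to 0.094. The mean of all probe sets took Ctse from 3.89 to 1.03 in saline, since its second probe set differed in the opposite direction (log2 -1.84, and -1.87 after APAP), and Mgst3 from 1.99 to 1.01. Values near the array medians, about 2.9, may limit the folds of genes such as Cidec.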

Other observations

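The comparison over both treatments, the strain tests near Psmb9, the tests on Txnrd1, the test of lipid droplet genes and the test of batch against the groups were chosen only after the results were seen.

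Over both treatments further transcripts differed between the genotypes. Of 23 interferon-stimulated genes 4 fell in livers labelled liver-null, though the mean of the list did not pass the exact permutation test (exact p = 0.06, adjusted p = 0.134). Among the 4 were Usp18, which removes the ubiquitin-like ISG15 (2.44-fold, adjusted p = 0.0249), Psmb9, an immunoproteasome subunit (1.74-fold, adjusted p = 0.0431), and Irf9 (log2 -0.62). The MHC class I genes H2-K1 (-0.36), H2-D1 (-0.43) and H2-Q10 (-0.41), chosen after their values were seen, fell with them. So did 5 probe sets that each match several genes of the histocompatibility complex (log2 -1.42 to -0.39), also chosen afterwards. Of 14 clock genes 2 fell, Bhlhe40 (2.41-fold) and the output regulator Dbp (1.95-fold). Of 14 bile acid synthesis genes 1 rose, the sterol 12-alpha-hydroxylase Cyp8b1 (2.05-fold), and 1 fell, Amacr (log2 -0.86). Of 15 transporters 2 rose and 2 fell, with Abcc3 among the rises and Slco1a1 (-0.79) and Slco1a4 (-1.20) the falls. Of 22 drug-metabolising cytochromes P450 1 rose, Cyp2c38 (2.91-fold).

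By camera, 26 lists did not pass over both treatments. Of the cell-type lists, 4 had means under 0.1 in size: Kupffer cell 0.00 (0 of 17 changed), sinusoidal endothelial 0.00 (0 of 20), cholangiocyte 0.07 (0 of 5) and lymphocyte and natural killer 0.07 (0 of 6). Lists with a mean above 0.1 in size were monocyte and neutrophil markers (0.32, 0 of 7 changed), heat shock (0.22), cytochrome P450 (0.21), glutathione and cysteine synthesis (0.17), cell cycle (-0.17), immediate early genes (-0.15), periportal markers (-0.13), fatty acid oxidation (0.12 with a median of -0.079), glycolysis (-0.11), bile acid synthesis (-0.11) and the acute phase response (0.37). The carry-over list had a mean of 0.43 with a median of -0.057, since Plin4 rose and Cela1 fell. Gluconeogenesis (0.10), endoplasmic reticulum chaperones (0.09), the thioredoxin system (0.09), cytokines (-0.09), transporters (-0.07), p53 targets (0.05), sulfotransferases (-0.04), clock genes (-0.04), UDP-glucuronosyltransferases (-0.02) and pericentral markers (-0.02) were closer to 0.

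Lists that passed camera there included the integrated stress response (1 of 18 genes rose, mean 0.37, adjusted p = 0.00185), metallothioneins and metal handling (2 of 9 rose, 0.50, adjusted p = 0.0122), interferon-stimulated genes (-0.33, adjusted p = 0.00042) and stellate cell markers (2 of 16 fell, -0.26, adjusted p = 0.000164). None passed with an estimated correlation.

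The arrays labelled liver-null had more Txnrd1 signal than the wild-type arrays. A wrong genotype label on some but not all arrays is argued against, since the lowest NRF2 list mean of the 6 arrays labelled liver-null exceeded the highest of the 6 wild-type arrays by 0.771. An exchange of the genotype labels on all arrays would leave a gap of the same size. The gap therefore does not test such an exchange, which stays open. The probe set may lie outside the deleted part of the gene, with the remaining locus transcribed more, as other NRF2 targets are. Its rise of 0.74 in saline lay beside the lower end of the risen NRF2 targets, 0.76 to 2.83, which does not decide it, because the position of the probe set was not used here.

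The 4 arrays of the second batch differed from the other 8 in 37.4% of genes. These sets were picked by the upper quartile of the same values, so a part of this difference follows from the choice. A difference in overall scale is argued against as the whole cause, since 15.6% of genes still differed after quantile normalization, counted on the same sets. That step acts on summarised probe sets and would not undo separate RMA runs, so whether the arrays were normalized apart stays open. Genotype or treatment is argued against by design, since the number of second-batch arrays differed by 0 between the groups. What set these arrays apart stays open, and no biological explanation was tested.

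Pparg, Cd36, Cidec, Fitm1 and Plin4 stood higher in livers labelled liver-null, and a wider fatty-liver program may lie behind them. The 11 tested other genes of lipid droplets and PPAR-gamma had a median log2 difference of -0.091 in saline and -0.166 after APAP. In limma 0 of them passed in either comparison. Their mean had intervals of -0.382 to 0.297 and -0.648 to 0.288, taken over the genes. These intervals treat the genes as independent and hold no variation between livers. The genes already seen to rise were left out of this set, which leans it towards no difference. The test therefore does not decide the hypothesis.

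DNA of another strain beside the targeted allele could also change nearby genes. Among the 100 tested genes nearest to Txnrd1 the odds ratio of changed genes was 1.61 in saline (Fisher's exact p = 0.469), 1.33 after APAP (Fisher's exact p = 0.534) and 0.892 over both treatments (Fisher's exact p = 1). At an unadjusted p under 0.05 the neighbours held more genes than the rest, 21% against 12.1% in saline, 11% against 9% after APAP and 28% against 16.9% over both treatments, shares that were not tested. Around Psmb9, in the major histocompatibility complex, it was 1.37 over both treatments (interval 0.489 to 3.13, Fisher's exact p = 0.457), with unadjusted shares of 23% and 16.9%. The 5 probe sets that match several histocompatibility genes are not among these counts. With so few changed neighbours these tests do not decide.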
